A study of Mus musculus with 6 samples.

How the data were processed

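RNA was extracted from TM4 cells with Trizol and sequenced from TruSeq RNA libraries, per the labels' protocols, which do not state whether the libraries kept strand. The data were 1 table with a column for each of 3 control and 3 VC libraries, and each column was matched to its sample by the group letter and number in its name. Alignment used HISAT2 and the mouse build GRCm39, per the submitters' processing notes; the tool that counted reads and the annotation release are not given in the sources used here. The deposited values are a non-negative signal with 3 decimals that behaves as a transcripts-per-million value multiplied by 1 factor per library: the column totals run from 966031 to 1058206, their geometric mean is 1000000, and the name of the deposited table points to TMM scaling by the authors. No low-expression filter had been applied, since 27930 of the 55414 genes were at 0 in every library.

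The gene models at hand were GENCODE release M21 on build GRCm38, an earlier build, and were used for gene symbols, exon lengths, GC content and exon overlaps only, so no coordinates are given. Symbols were found for 52081 of 55414 identifiers and lengths for 52133. Multiplying each value by its gene's exon length gave whole multiples of 1 step per library for 98.77% to 98.93% of values within 0.1 read, tested up to 1000 reads where rounding leaves an error under 0.05 read. The recovered reads summed to between 20408396 and 22316777 per library, and they were used to judge depth, to check for duplicated libraries by chi-square and for 2 alternatives, never for the main result.

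For the main comparison, genes with a value of 1 or more in at least 3 of the 6 libraries were kept (13972 genes), log2(value + 1) was taken, and VC was compared with control in limma 3.58.1 (R 4.3.3) with empirical Bayes and an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate and no replicate block was used. Fold changes are VC minus control on the log2(value + 1) scale. Gene lists were tested with limma's camera at a preset correlation of 0.01 where at least 5 members passed the filter, 27 of 30 lists, with adjustment over these 27. The limma adjusted p of single list members was computed over all genes and, separately, adjusted over the list alone. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

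Before the data were examined, the groups, the main test, 30 gene lists with 1102 entries (1091 of them matched to the table) and most alternatives were fixed, as was the rule for the genes named. That rule takes, among genes past the adjusted threshold whose 3 VC values lie on one side of the 3 control values and whose name is not a predicted or clone name, the 12 largest rises and the 12 largest falls; from each list up to 4 members past the threshold with the smallest adjusted p; and 13 genes given whatever their test (Slc23a1, Slc23a2, Sox9, Wt1, Gata4, Cldn11, Gja1, Tjp1, Ocln, Vim, Amh, Bcat1 and Bcat2). Members named beside these were chosen after their values were seen, and 1 gene that the rule takes is not reported here. The lists covered vitamin C transport and recycling, ascorbate-dependent hydroxylases and demethylases, collagen and extracellular matrix, antioxidant genes, cholesterol and SREBP2 targets, hypoxia, glycolysis, ATF4 targets, the unfolded protein response, valine and branched-chain amino acid catabolism, Sertoli, junction, Leydig, smooth muscle, germ cell, macrophage and endothelial genes, cell cycle, histones, p53, interferon, inflammation, immediate early genes, TGF-beta, iron, heat shock, lysosome, mitochondrially encoded genes, ribosomal proteins and noncoding RNAs.

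The procedure was tested on simulated data in 20 runs over 13772 genes for VC against control. Counts were drawn for each gene independently, at the depth of these libraries and with 1 dispersion (0.00158) for all genes. In these runs limma recovered 57.1% of genes changed 1.3-fold, 79.6% at 1.5-fold, 92.6% at 2-fold and 97.4% at 3-fold, and 6.27% of all calls were false. Camera recovered 100% of simulated lists of 30 genes raised 1.2-fold, and 1.5% of unchanged lists had an unadjusted p under 0.05. The simulation held no differences in dispersion between genes, no library that stood apart and no correlation within lists. These rates are therefore not error rates of the real data. Alternatives changed the pseudocount, the filter, the scaling, the prior variance, library weights, the replicate block and the libraries included, and tested lists with an estimated correlation and with fry. A limma-voom fit of the recovered reads, a filter on reads, robust empirical Bayes and the removal of trends with gene length, GC content and level were added after the data were seen. The reads limit precision for low genes: 6 called genes had a mean under 10 reads per library.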

Results

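Gene expression was measured by RNA sequencing in TM4 cells, a mouse cell line derived from testis and used as a model of Sertoli cells, the somatic cells that surround and support developing germ cells in the seminiferous tubule. The 6 libraries fell into 2 groups of 3, a control group and a group labelled VC. The labels disagree on the agent: the titles point to vitamin C, while a sample characteristic and the design text name valine, so the treated group is called VC throughout. No dose or exposure time was given. Nothing in the labels says that the replicates came from separate cultures. Limma's p-values for single genes thus measure the spread between these 6 samples, which may be technical. Camera at the preset correlation weighs a list against the spread across genes, so its p-values do not measure the spread between samples.

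The deposited table held a value for each of 55414 Ensembl gene identifiers in each library, on a transcripts-per-million scale with a cross-library factor. The values came out as whole multiples of the worth of 1 read, which put the depth at 20408396 to 22316777 reads per library over genes of known length. Between 21282 and 21704 genes had a value above 0. Log2 values correlated at Pearson's r of 0.9859 to 0.9876 within groups and 0.984 to 0.9864 between groups, across genes, which are not independent replicates. No pair of libraries agreed within sampling noise. Control replicate 3 stood apart from the others: the chi-square per degree of freedom of its reads against another library was 9.59 to 17.3, against 2.78 to 7.31 for pairs without it.

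The comparison of VC with control asks how the agent altered the transcriptome of these cells. Genes of cholesterol synthesis, interferon-stimulated genes and lysosomal genes were higher in VC, and genes of the contractile cytoskeleton were lower, by limma's camera. The lysosome call was lost at adjusted p = 0.249 with an estimated correlation and the contractile call at adjusted p = 0.0968 with an estimated correlation. Ribosomal protein and mitochondrially encoded genes, which can track RNA quality, were also lower by camera, and lost their calls at adjusted p = 0.496 and adjusted p = 0.408 with an estimated correlation. Changes of single genes were small. Lss, which closes the sterol ring, rose from 20.1 ± 1.01 to 28.6 ± 0.407 (mean value ± SD, n = 3 per group), and Ifit1, an interferon-induced antiviral protein, rose from 16.4 ± 0.608 to 26.5 ± 1.99. Acta2, smooth muscle actin, fell from 612.9 ± 29.3 to 381.7 ± 4.39.

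Of 13972 genes that passed the expression filter, limma called 96 at an adjusted p under 0.05, with 60 higher and 36 lower in VC. In each of the 96 genes the 3 VC values lay on one side of the 3 control values. That held for 3570 tested genes, or 25.6%, where chance gives 10%. Only 6 called genes differed at least 2-fold on the log2(value + 1) scale, which understates the change of low genes, and the median size of a called change was 0.39 log2 units. Of the 6, Scand1 fell on 236 to 242 recovered reads in control and 56 to 95 in VC, while Mir7664, Gm25364, Gm48931 and Gm23706, called higher, and Gm45027, called lower, had at most 5 reads in any library; the predicted genes among them were picked after their values were seen. Scaling the libraries to equal totals gave 182 higher and 35 lower genes, moving the share of higher calls from 62.5% to 83.9%. It also moved the median log2 fold change of all tested genes from 0.012 to 0.078. Each list or gene value given below for equal totals includes this shift of all genes. The number of called genes was not kept when 1 of 5 of the 6 libraries was left out. Limma called 1 gene without control replicate 1, 0 without control replicate 2, 0 without VC replicate 1, 0 without VC replicate 2 and 1 without VC replicate 3. In these fits 1607 to 2271 genes had an unadjusted p under 0.05, against 2410 with all libraries. A fit with fewer libraries also has less power, so a fall from 96 does not by itself show dependence on a particular library. Without control replicate 3 limma called 83 genes, 60 of them among the 96, and 2478 had an unadjusted p under 0.05. That fit holds as many libraries as those without control replicates 1 and 2. The number of libraries alone therefore does not account for 83 calls against 1 and 0, and it mattered which control was left out.

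The list of cholesterol biosynthesis and SREBP2 targets, the sterol-responsive programme, was higher in VC. All 33 measured members had a log2 fold change above 0, with a median of 0.23. Of these, 8 rose when adjusted over all genes and 29 when adjusted over the list alone, and 25 did not pass over all genes. Lss rose by 0.49 log2 units (SE 0.049, limma adjusted p = 0.0189), Mvd, a decarboxylase of the mevalonate pathway, by 0.40 (SE 0.035), Cyp51, the lanosterol demethylase, by 0.38 (SE 0.028) and Idi1, the isopentenyl isomerase, by 0.34 (SE 0.031). The camera test in limma placed the list above the other genes at an adjusted p of 3.69e-20, and the call held at adjusted p = 0.00603 with an estimated correlation.

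The interferon response list was also higher, with 37 of 38 measured members above 0 and a median log2 fold change of 0.40, which was 0.21 with a pseudocount of 5. Here 6 members rose when adjusted over all genes and 25 when adjusted over the list alone, and none fell in either count by limma. Usp18, the protease that removes Isg15 from proteins, rose by 0.73 (SE 0.10) from a low value of 1.85 ± 0.049 to 3.72 ± 0.251. Ifit1 rose by 0.66 (SE 0.064), the chemokine Cxcl10 by 0.65 (SE 0.086) and the ubiquitin-like modifier Isg15 by 0.56 (SE 0.079), with limma adjusted p between 0.0189 and 0.0391. Oasl1, an oligoadenylate synthetase-like protein, rose by 0.53 (SE 0.077) and the chemokine Ccl5 by 0.50 (SE 0.073). Camera gave an adjusted p of 1.85e-18 for the list, and adjusted p = 0.00603 with an estimated correlation.

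Among lysosome and autophagy genes, 7 of 44 measured members rose and 1 fell when adjusted over all genes, and 23 rose and 1 fell when adjusted over the list alone. Gpnmb, a lysosomal membrane glycoprotein, rose from 15.1 ± 0.917 to 24.4 ± 1.99, by 0.66 log2 units (SE 0.075). The sialidase Neu1 rose by 0.40 (SE 0.048) and Atp6v1b2, a subunit of the proton pump, by 0.25 (SE 0.033). Map1lc3a, one of the LC3 proteins of autophagosomes, fell by 0.45 (SE 0.059). The list's median was 0.13, or 0.204 with equal totals, where the median of all genes was 0.078. The list was higher by camera at an adjusted p of 1.44e-08, and adjusted p = 0.249 with an estimated correlation.

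**Figure D1:**
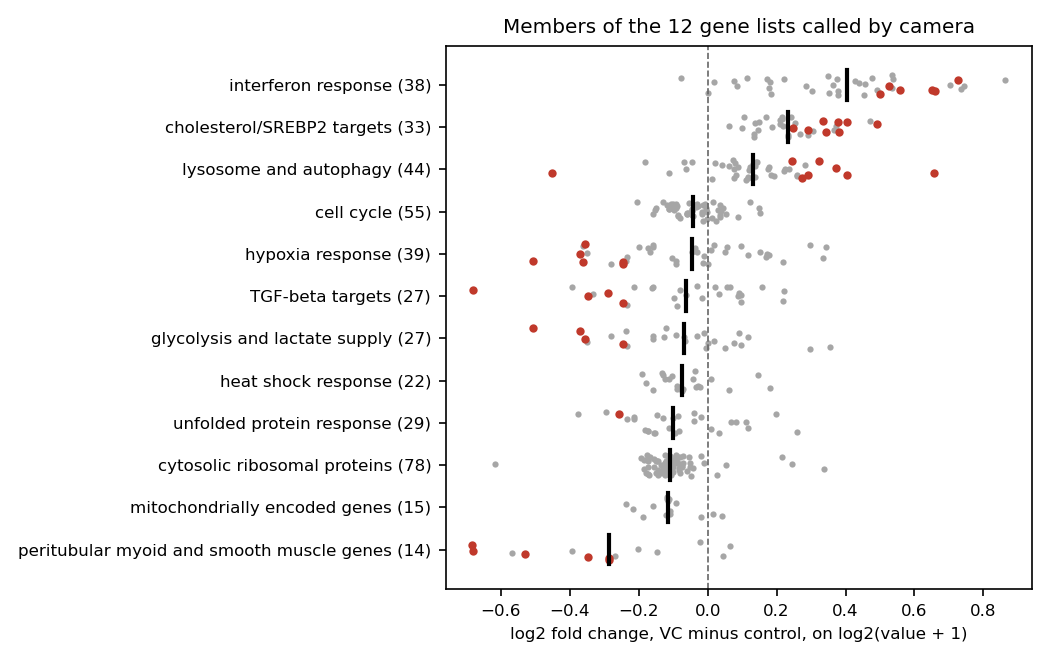
Log2 fold change (VC minus control, on log2(value + 1)) of each measured member of the 12 lists called by camera, with the number measured in brackets; red points passed limma's adjusted threshold over all genes, grey points did not, and black bars are list medians. The medians run from -0.29 for smooth muscle genes to 0.40 for interferon genes. With libraries scaled to equal totals, the medians of the hypoxia, glycolysis, TGF-beta and cell cycle lists lie above 0, but below the 0.078 of all genes. The median of mitochondrially encoded genes lies above 0 after quantile normalization.

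Genes of peritubular myoid and smooth muscle cells were lower in VC. Of 14 measured members 6 fell when adjusted over all genes and 10 when adjusted over the list alone, with a median log2 fold change of -0.29, which was -0.174 without a filter. Acta2 fell by 0.68 (SE 0.041), the myosin light chain Myl9 by 0.68 (SE 0.054), the enteric actin Actg2 by 0.53 (SE 0.068) and the tropomyosin Tpm1 by 0.29 (SE 0.035), with limma adjusted p from 0.0111 to 0.0348. Srf, the transcription factor that drives many actin genes, fell by 0.35 (SE 0.048). Camera placed the list below the other genes at an adjusted p of 4.19e-09, and adjusted p = 0.0968 with an estimated correlation. Acta2 belongs also to the list of TGF-beta targets, in which 4 of 27 members fell over all genes, and 2 rose and 6 fell when adjusted over the list alone. Among the other members, Ccn2, a matricellular growth factor, fell by 0.29 and Id3, an inhibitor of helix-loop-helix factors, fell by 0.35. The TGF-beta list was lower by camera (adjusted p = 0.0161, and adjusted p = 0.263 with an estimated correlation). The median of this list, -0.06, became 0.001 with libraries scaled to equal totals, where the median of all genes was 0.078. Camera no longer called it without control replicate 2 (adjusted p = 0.101), and its median was -0.018 without VC replicate 2.

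Glycolysis and lactate supply, by which Sertoli cells feed germ cells, was lower as a list. Of 27 members, 4 fell over all genes, and 3 rose and 10 fell when adjusted over the list alone. Pfkl, a phosphofructokinase subunit, fell by 0.51 (SE 0.045), Pgk1 by 0.37 (SE 0.049), Ldha, a lactate dehydrogenase subunit, by 0.36 (SE 0.052) from 1247 ± 75.7 to 974.2 ± 30.4, and the enolase Eno1 by 0.25 (SE 0.035). Camera gave an adjusted p of 0.00116, and adjusted p = 0.421 with an estimated correlation. The list's median of -0.07 became 0.005 with libraries scaled to equal totals, where the median of all genes was 0.078 and camera still called the list lower. In the list of hypoxia (HIF) targets 6 of 39 members fell over all genes, and 6 rose and 16 fell when adjusted over the list alone. They included these 4 glycolytic genes and P4ha1, a collagen prolyl hydroxylase, which fell by 0.36 (SE 0.044). Camera called the hypoxia list lower at an adjusted p of 0.00405, and adjusted p = 0.496 with an estimated correlation. Its median went from -0.05 to 0.025 with libraries scaled to equal totals, and its call was lost without VC replicate 2 (adjusted p = 0.0645, median -0.0023). The hypoxia median was -0.014 without control replicate 1, -0.10 without control replicate 2, -0.025 without control replicate 3 and -0.10 without VC replicate 1.

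**Figure D2:**
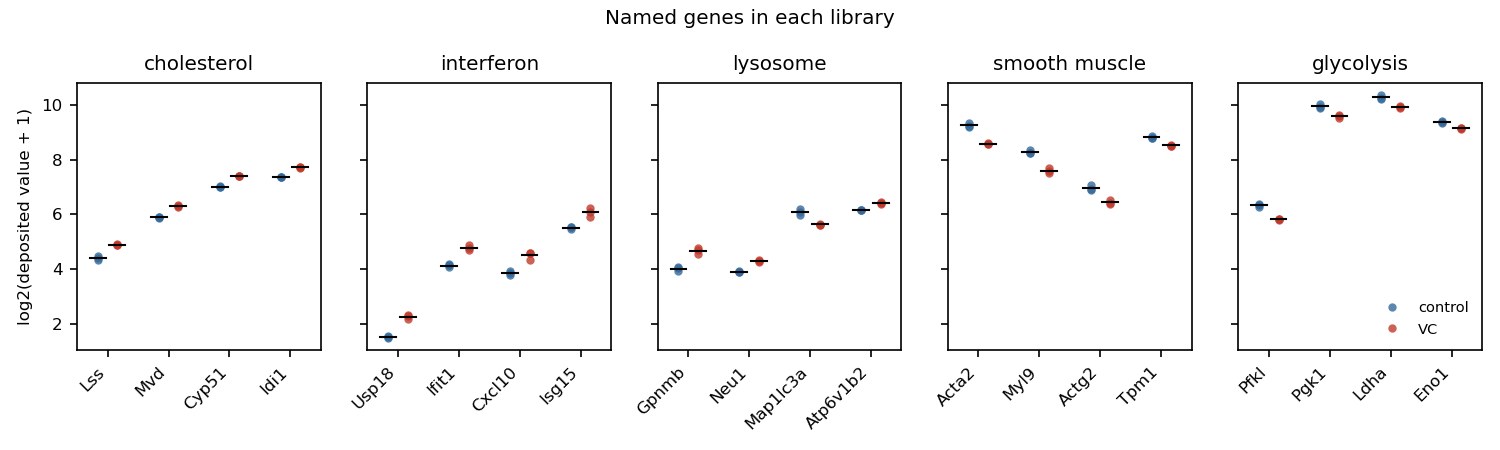
Log2(deposited value + 1) of the named genes of 5 lists in each library; blue points are the 3 control libraries, red points the 3 VC libraries and black bars group means. In each gene shown, the 3 VC values lie on one side of the 3 control values, as for Acta2 (588.9 to 645.6 in control, 378.0 to 386.5 in VC) and Isg15 (42.6 to 45.7 in control, 58.8 to 73.1 in VC).

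Genes of the unfolded protein response of the endoplasmic reticulum were lower as a list, with a median of -0.10 over 29 members. It was -0.05 after quantile normalization and -0.03 with equal totals, where the median of all genes was 0.078. Hspa5, the chaperone BiP, fell by 0.26 (SE 0.037) over all genes, while 2 members rose and 10 fell when adjusted over the list alone. Camera gave an adjusted p of 0.000218, and adjusted p = 0.293 with an estimated correlation. No member of the heat shock list (22 measured) or the cell cycle list (55 measured) passed over all genes, and 3 heat shock members fell when adjusted over the list alone, against 0 of the cell cycle list. Both were lower by camera, heat shock at 0.000687 and cell cycle at 0.00152, with adjusted p = 0.424 and adjusted p = 0.147 with an estimated correlation. The correlation estimated was 0.27 for heat shock and 0.007 for cell cycle, the latter below the preset 0.01. The cell cycle median of -0.04 became 0.029 with libraries scaled to equal totals and -0.026 without control replicate 2, and both calls were lost after quantile normalization.

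Lists that can track RNA quality also moved with the group. The 78 cytosolic ribosomal protein genes had a median of -0.11 and the 15 mitochondrially encoded genes a median of -0.12, with no member past limma's threshold over all genes. When adjusted over the list alone, 0 ribosomal protein genes and 3 mitochondrial genes fell. Camera adjusted p was 2.17e-11 for ribosomal proteins (adjusted p = 0.496 with an estimated correlation) and 7.08e-05 for mitochondrial genes (adjusted p = 0.408 with an estimated correlation). Without control replicate 3 the ribosomal protein median was -0.051, and with equal totals the medians were -0.038 and -0.044, against 0.078 for all genes. After quantile normalization neither list was called, and the mitochondrial median was 0.007. The list of nuclear-retained and small noncoding RNAs was not called (6 measured, adjusted p = 0.518), with 1 higher and 1 lower when adjusted over the list alone. With the tested genes split by total exon length into 4 groups of like size, the median log2 fold change went from -0.038 in the shortest to 0.054 in the longest. Split in the same way by mean level, the median was 0.041 in the lowest group and -0.037 in the highest. Sets of genes matched on both were not drawn for the hypoxia, glycolysis, unfolded protein, heat shock, TGF-beta, cell cycle or mitochondrial lists.

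Sertoli cell genes were not called by camera (adjusted p = 0.105) but were called higher by fry, which asks whether the genes move 1 way and does not compare them with other genes (adjusted p = 0.0136). Of the 45 genes in the list only 19 passed the expression filter, so both tests cover a part of it. Of these 19 measured members none passed limma's threshold over all genes and 3 rose when adjusted over the list alone. Sox9, which directs Sertoli differentiation, was at 3.01 ± 0.239 in control and 3.70 ± 0.403 in VC (limma adjusted p = 0.348), Gata4 at 19.2 ± 0.631 and 21.8 ± 0.442 (adjusted p = 0.139), and the hormone gene Amh at 0.97 ± 0.098 and 0.659 ± 0.440 (adjusted p = 0.575). Vim, the intermediate filament protein vimentin, was at 1273 ± 49.6 and 1204 ± 34.0 (adjusted p = 0.387). Wt1 was listed at 0 in all 6 libraries, as were the list members Fshr, Dmrt1, Shbg and Nr0b1, picked after their values were seen. Cldn11, a tight junction protein of Sertoli cells, was at 0.135 in control replicate 2 and 0 in the other libraries, and Ocln reached at most 0.092. The junction list had no member past the threshold over all genes (31 measured), 2 rose and 2 fell when adjusted over the list alone, and camera gave 0.917. Its values included Gja1, connexin 43, at 127.0 ± 3.30 in control and 138.7 ± 4.54 in VC (limma adjusted p = 0.176) and Tjp1 at 43.6 ± 5.97 and 45.1 ± 0.686 (adjusted p = 0.788). Of markers of other cell types, 2 germ cell genes (Gfra1 and Sycp1), 2 macrophage genes (Cd14 and Cd68) and 3 endothelial genes (Cdh5, Ecscr and Eng) passed the filter, too few for a list test, and none of the 7 passed limma's threshold over all genes or adjusted over the list alone.

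The lists tied most closely to the possible agents were not called by camera on the deposited scale, and the calls of 2 of them changed with the scaling. Camera asks for a shift 1 way. Fry's mixed test, for change either way, gave adjusted p of 4.98e-05 for vitamin C transport, 0.00102 for hydroxylases and 0.00937 for valine catabolism. It passed every list tested except histones (0.742) and ribosomal proteins (0.147), so it does not single these lists out. Among vitamin C transport and recycling genes 0 of 14 passed over all genes, 1 rose and 1 fell when adjusted over the list alone, and camera gave an adjusted p of 0.917. The ascorbate transporter gene Slc23a2 was at 13.7 ± 0.939 in control, with a log2 fold change of 0.12 (SE 0.070, limma adjusted p = 0.414), and Slc23a1 stayed below the filter with values from 0.632 to 1.81. Of 42 ascorbate-dependent hydroxylases and demethylases P4ha1 alone fell, over all genes and when adjusted over the list alone (camera 0.704). In the collagen list 1 of 39 members fell over all genes and 2 when adjusted over the list alone (camera 0.518), and in the antioxidant list the metallothionein Mt1 rose by 0.39 (SE 0.039), while 2 of 47 rose and 2 fell when adjusted over the list alone (camera 0.135, and 0.0333, lower, without control replicate 2). The list of valine and branched-chain amino acid catabolism had 0 of 32 members past the threshold over all genes and 1 that rose when adjusted over the list alone (camera 0.253, and called higher at 0.0474 with equal totals and at 0.0417 without control replicate 3). Its transaminases Bcat1 (80.3 ± 1.97 in control, 77.5 ± 1.72 in VC) and Bcat2 (14.4 ± 1.39 and 15.2 ± 0.330) did not pass (limma adjusted p = 0.515 and 0.644). ATF4 targets, which respond to amino acid supply, had 0 of 44 members past the threshold in either count (camera 0.181). Camera called the ATF4 list higher at 0.00549 after quantile normalization, 0.0131 with equal totals, 0.0103 with trends with gene length, GC content and level removed, and 0.0417 without control replicate 3.

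Of the remaining lists none was called by camera on the deposited scale. Inflammatory and NF-kB targets held 3 members that rose over all genes and 4 when adjusted over the list alone, out of 26 (camera 0.446; fry 0.00222, higher, with 13 members above 0, 13 below and a median of 0.010), of which Cxcl10 and Ccl5 are also interferon list members and Il1rl1, the interleukin-33 receptor, rose by 0.53 (SE 0.039) from 144.6 ± 6.30 to 208.9 ± 2.31. Among 33 immediate early genes Ccn2, Srf and Jund fell over all genes, 4 rose and 6 fell when adjusted over the list alone (camera 0.518), and Jund, an AP-1 subunit, fell by 0.74 (SE 0.11). Iron handling held Steap3, an endosomal ferrireductase that rose by 0.39 (SE 0.047), and 2 of 21 rose when adjusted over the list alone (camera 0.0572, fry 0.0136). Camera called the iron list higher at 0.0109 after quantile normalization, 0.0217 with equal totals, 0.0447 with array weights, 0.0149 with trends removed, 0.044 without control replicate 3 and 0.0447 without VC replicate 1. Leydig cell genes (10 measured) and histones (23 measured) had no member past the threshold in either count (camera 0.518 and 0.28, with histones called lower at 0.00745 with equal totals), and of 25 p53 targets none passed over all genes while 2 rose and 1 fell when adjusted over the list alone (camera 0.917). The median, mean and camera direction differed in sign for the vitamin C transport list (-0.001, 0.023, up), the collagen list (-0.024, 0.002, down) and the junction list (-0.010, 0.015, down).

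Outside the lists, Xdh, the purine oxidase xanthine dehydrogenase, rose from 9.22 ± 0.397 to 15.6 ± 0.820 (log2 fold change 0.70, SE 0.062, limma adjusted p = 0.0167). The fatty acid transporter Slc27a1 rose by 0.60 (SE 0.073), Apol9b, an apolipoprotein L family member, by 0.56 (SE 0.070) and the lysosomal peptidase Dpp7 by 0.51 (SE 0.069). Scand1 had the largest fall of all called genes, from 39.6 ± 1.43 to 13.2 ± 3.64 (by 1.55, SE 0.18, limma adjusted p = 0.0288). The LIM protein Fhl1 fell by 0.77 (SE 0.079), Apol10b fell by 0.55 (SE 0.071), Pop1, a subunit of RNase P and RNase MRP, fell by 0.52 (SE 0.039), and Sap30, part of the Sin3 histone deacetylase complex, fell by 0.44 (SE 0.063). The mitochondrial tRNA gene mt-Ty fell by 0.85 (SE 0.095) on 10 to 11 recovered reads in control libraries and 5 to 6 in VC libraries. The microRNA gene Mir7664 was called higher but was listed at 0 in all control libraries and rested on at most 2 reads in any VC library, so no fold is given. Apol9b shares sequence with its paralog Apol9a, and Scand1 and Jund overlap exons of genes on the opposite strand over 40.4% and 52.6% of their exon length, so their values are uncertain where reads could be shared. The opposite-strand genes had mean values of 0.95 (Cnbd2, beside Scand1) and 0.0 (Gm11175, beside Jund).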

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

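The tests added after the results were seen are limma-voom on recovered reads, the filter of 10 reads, robust empirical Bayes and the removal of length, GC and level trends. The camera calls were steadier than the gene calls, which is partly a property of the test. Every refit kept camera's preset correlation, and with the replicate block camera called 12 lists where limma called 0 genes. The refits without the intensity trend and with robust empirical Bayes left the camera test unchanged, so they could not alter a list call. In all 20 refits 6 of the 12 called lists (cholesterol, interferon, lysosome, smooth muscle, glycolysis and unfolded protein response) kept their call and direction. The ribosomal protein, heat shock and mitochondrially encoded lists lost theirs after quantile normalization and trend removal, where the mitochondrial list also turned, the cell cycle list also with equal totals, the hypoxia list without VC replicate 2, and the TGF-beta list with the stricter filter and without control replicate 2. None of the 43 called named genes changed direction in any refit, but in many refits none could. Their VC values all lay on one side of their control values, so leaving out a library cannot turn the sign. Refits that changed only the filter, the prior variance or the replicate block leave the fold change as it was. Many of these genes lost their call: 30 without a filter and 41 without the intensity trend. Of those tested, 42, 43, 15, 42, 42 and 41 lost it without control replicates 1, 2 and 3 and VC replicates 1, 2 and 3. Camera called 2 lists with an estimated correlation. That version gave larger adjusted p-values even where the estimate lay below the preset 0.01, as for cholesterol (-0.007), interferon (-0.005) and cell cycle (0.007). A call lost there thus need not mean that the members were correlated. Fry's test for change 1 way called 10, of which 7 were also called by camera. It did not call hypoxia (0.148), glycolysis (0.057), heat shock (0.0592), mitochondrially encoded (0.0681) or ribosomal protein genes (0.202). It called Sertoli (0.0136), inflammatory (0.00222) and iron genes (0.0136). The causes of the changes below were not tested, and depth limits the genes of few reads.

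The fit reported gave 60 higher, 36 lower and 6 genes at least 2-fold changed. Without a filter the higher and lower genes numbered 20 and 10, with the stricter filter 112, 71 and 3, without the intensity trend 4 and 2, with array weights 153, 101 and 16, with the filter of 10 reads 109, 72 and 2, with trends removed 184, 82 and 11, and with limma-voom 341 and 205, which shared 86 of the 90 main calls it tested. Equal totals gave 182 higher and 12 at least 2-fold changed, and a pseudocount of 5 gave 1 at least 2-fold changed. Leaving out 1 library at a time gave 0 to 52 higher, 0 to 31 lower and 0 to 4 at least 2-fold changed; the 83 calls without control replicate 3, 60 of them shared with the 96, were the most. The count tests planned for a table of raw counts (edgeR and DESeq2) were not run, because the deposited values are not counts. Limma-voom was fitted to the recovered reads in their place.

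The replicate block gave 0 higher, 0 lower and 0 at least 2-fold changed genes by limma, with 2039 genes at an unadjusted p under 0.05. Same-numbered libraries did not deviate together (correlations of deviations across genes -0.019, -0.011 and 0.005), and not every library correlated best with its own number. No pairing by number was seen, but these values cannot show that same-numbered libraries were prepared apart.

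Values that turned, relative to 0 for genes and to the other genes for lists, were near 0 in genes and lists not called, except mitochondrially encoded genes, whose medians were 0.007 after quantile normalization and 0.043 with trends removed. Quantile normalization gave 0.021 for Vim, and list medians of -0.002 for hydroxylases, 0.038 for collagen and 0.019 for junctions. Equal totals gave 0.021 for Bcat1 and 0.061 for junctions, median-of-ratios -0.012 for vitamin C transport, the stricter filter 0.025 for hydroxylases, array weights -0.016 for Tjp1 and the replicate block 0.001 for p53. Trend removal gave -0.03 for hydroxylases and -0.013 for immediate early genes, and limma-voom 0.054 for noncoding RNAs. Over the fits that left out 1 library, Tjp1 ran from -0.057 (without control replicate 3) to 0.129, and the list medians of vitamin C transport from -0.007 to 0.024, hydroxylases from 0.008 to 0.051, collagen from -0.051 to 0.011, junctions from -0.013 to 0.03, p53 from -0.02 to 0.005 and noncoding RNAs from -0.102 to -0.008. In these lists camera's direction, relative to the other genes, turned in 1 to 3 of the 6 such fits, and no turned list was called.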

Other observations

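The tests of other splits, single libraries, control replicate 3, length and level trends, macrophages, myoid cells and hypoxia genes outside glycolysis were chosen only after the results, or part of what decides them, were seen; the further lysosomal set and the SRF set were written before their own values were seen. A second list of lysosomal genes, none called and none in the fixed list, was written to ask as a hypothesis whether the rise of lysosomal genes was wider. Of its 41 measured genes 35 had a log2 fold change above 0, with a median of 0.146, and limma's camera placed it above the other genes at an adjusted p of 1.22e-07 over 3 such sets, and at adjusted p = 0.0087 with an estimated correlation. Its values included the folliculin partners Fnip1 (32.4 in control, 41.4 in VC) and Fnip2 (20.6 and 28.9), and the thioesterase Ppt1 (40.6 and 48.8), none of which passed limma's threshold over all genes. Genes called higher outside the lists, picked after their values were seen, included further lysosomal proteins: the cystine exporter Ctns rose by 0.50 log2 units, the peptidase Tpp1 by 0.33 and folliculin (Flcn), which acts at the lysosomal surface, by 0.42. A wider rise of lysosomal genes is consistent with these values, as a hypothesis.

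The hypoxia list was lower in VC, and a hypothesis is that its glycolytic members alone account for that. The 23 members outside the glycolysis list, including P4ha1, which fell, split into 11 above and 12 below 0, with a median of -0.013 against 0.012 over all genes, and camera gave an adjusted p of 0.402. The set did not pass, which does not show that it was level with the other genes, so the question stays open. Vegfa was at 48.2 in control and 47.8 in VC.

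The cholesterol, interferon and lysosome lists were higher in VC by camera, the lysosome list with a call lost at adjusted p = 0.249 with an estimated correlation. A trend of fold change with gene length and level is argued against as their whole source: 0 of 1000 sets of other genes matched on length and level had a median as high as the cholesterol list, 0 as high as the interferon list and 0 as high as the lysosome list, and with trends removed the medians were 0.238, 0.356 and 0.142, all still called by camera at the preset correlation. Dependence on 1 library is argued against as well, since each VC library lay above each control library in all 3 lists. Median deviations of the lysosome list were -0.109 to -0.023 in control and 0.061 to 0.082 in VC. The largest camera adjusted p of these lists, at the preset correlation, over the 6 fits that left out a library was 6.87e-06. That p adds little, since camera at this setting called 11 to 15 lists in each such fit. Macrophages in the VC cultures are argued against for the interferon and lysosome lists, as Lyz2, Tyrobp, Laptm5, C1qa, C1qb and C1qc reached at most 0.185 in any VC library. The agent, a difference in how the VC cultures were handled and chance stay open.

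Smooth muscle genes were lower in VC by camera, a call lost at adjusted p = 0.0968 with an estimated correlation. None of the matched sets (0 of 1000) had a median as low, and with trends removed the median was -0.256, which argues against the length and level trend as the whole source. Myoid cells in the control cultures are argued against by Myh11, Des, Synpo2 and Lmod1, which reached at most 0.998 in any control library beside 612.9 for Acta2. A candidate explanation is lower activity of the transcription factor Srf in VC: 24 other SRF and actin cytoskeleton genes, none called and none in the smooth muscle list, were lower as a set (18 below 0, median -0.098, camera adjusted p = 4.29e-05, and adjusted p = 0.0473 with an estimated correlation). Actb was at 4366 in control and 3808 in VC without passing limma's threshold, and the SRF hypothesis was tested on the same libraries in which it arose. The set mixes SRF genes with general actin genes, so it cannot tell Srf activity from a wider change of actin genes. The list of immediate early genes, which includes Srf, was not called by camera (adjusted p = 0.518).

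Ribosomal protein genes were lower in VC, with a median of -0.110, and the camera call was lost at adjusted p = 0.496 with an estimated correlation. Much of the difference lay in control replicate 3, the library that stood apart: the members' median deviation was 0.175 there, -0.005 and 0.002 in the other controls and -0.075 to -0.036 in VC. Without it the median was -0.051, called by camera at the preset correlation (adjusted p = 1.15e-06; largest over all 20 refits 0.119) but not with an estimated one (unadjusted p = 0.223), so that library stays open as the source. The length and level trend may account for much of it: matched sets of other genes had a median of -0.075, 95% of them between -0.095 and -0.051, and removing the trends left a median of -0.023 and ended the camera call, because the fold itself shrank. Only 1 of 1000 matched sets was as low as the ribosomal proteins, however, so the trend and a change of these genes cannot be told apart here.

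The 3 against 3 design makes 10 splits of the libraries, too few for a share under 0.05. In 1 of the 10 splits, the real one, limma called 96 genes, and the highest other split called 2. At least 2-fold changed genes numbered 6 in the real split, matched by 1 of 10 splits (itself), and at most 2 in the others. Camera called 12 lists in the real split (1 of 10 with as many) and 3 to 8 in each of the other 9. At the preset correlation camera thus called several lists under every grouping of these libraries. Each of the other 9 splits mixes the labels unequally, so part of any VC difference stays in it, and these calls need not all be false. The 1.5% of unchanged simulated lists with an unadjusted p under 0.05 came from genes drawn independently and is not a like figure.

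An abundant gene without a symbol, ENSMUSG00002076173, singled out after its values were seen, was at 6998, 6892 and 6373 in the control libraries and at 6023, 5074 and 941.4 in the VC libraries, and did not pass limma's threshold (adjusted p = 0.418). Small RNA genes called higher on few reads were Mir7664 with 2, 1 and 1 reads in the VC libraries, Gm25364 with 2, 2 and 2, and Gm23706 with 1, 1 and 1, all at 0 in control.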
